A study of Mus musculus with 2 samples.

How the data were processed

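Gene expression was measured on 2 Affymetrix Mouse Gene 1.0 ST arrays, 1 of bone marrow pDCs from Runx2-deficient fetal liver chimeras and 1 of wild-type pDCs, which makes 2 groups of 1 sample. The deposited values are linear intensities, from 15.3 to 20364, 1 value per probe set and array. Per the submitters' processing notes the authors used RMA (robust multi-array average, which corrects background, equalises the probe intensity distributions of the arrays and summarises probes); RMA normally reports log2 values, and the deposited column is on a linear scale. Which arrays were normalised together, the software, its version and the annotation are not given in the sources used here. RMA compresses differences of dim probe sets, and the deposited table carries no detection call and no probe-level spread, so background could not be set per gene. The number of arrays limits the precision: with 1 per group no test across samples is possible, and the spread between mice, between pools of mice and between hybridisations is unknown. The labels do not say how many mice gave each sample.

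Values were taken to log2 and the wild-type value was subtracted from the Runx2-deficient value. A fold is the ratio of the 2 linear intensities. Of 35556 probe sets, 21789 have exactly 1 gene symbol in the platform annotation used, 1621 have several and 12146 have none; only the first kind was named, and 21698 of these matched the RefSeq gene table by gene identifier, which changed 0 symbols. The annotation can be old, and a probe set without a name here may still measure a gene. Where a gene had several probe sets (999 of 19938 genes), the one with the highest mean of both arrays was used. Among genes 2-fold apart, 12 had several probe sets; 8 of these did not show 2-fold on all of them, and in 1, Adck1, they had opposite signs (0.019 and -1.80). A gene passed the brightness filter where it was at or above the median of all named genes on at least 1 array, 7.61 on the wild-type and 7.54 on the Runx2-deficient array in log2 units.

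Counts of differing genes used a threshold of 2-fold, without a test. The 28 gene lists were fixed before the data were examined, as were the main settings. They cover the Runx family, the 4 markers stained for the sort (CD11c is not in the stated gate), pDC-enriched and conventional dendritic cell genes, MHC class II presentation, dendritic cell transcription factors, chemoattractant receptors, adhesion, TLR7 and TLR9 signalling, interferon-stimulated genes, cytokines, cell cycle, apoptosis, unfolded protein response, osteoblast targets of Runx2, ribosomal and mitochondrial genes, immediate-early genes, sex-linked genes, and markers of B, plasma, T, NK, neutrophil, monocyte, erythroid, basophil and progenitor cells. Some genes are in more than 1 list. All measured members entered, also those below the brightness filter; members without a probe set of their own were left out. Each list's median difference was set against 10000 random lists of the same size, drawn from 20 bins of mean expression, and its percentile describes these 2 arrays only. It gives no p-value, and it assumes that genes vary independently, which co-regulated genes do not.

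Named genes follow a rule fixed beforehand: the Runx genes, the stained markers and Ccr2, Cxcr4, Tcf4, Irf8 and Siglech; the 12 genes with the largest difference in each direction past the filter, skipping antigen receptor genes, predicted gene models and olfactory receptors; and up to 3 list members in each direction. The rule limits the genes named in the results, and not each of the 166 genes it allows is printed; genes named in the further observations were picked outside it after the values were seen or came out of the chromosome scans, and Adck1 is named above for its probe sets. Differences were also simulated as normal values, with a robust spread per expression bin taken from the difference between these 2 arrays. There, 100% of genes planted at a log2 difference of 1.5 and 6.0% of those planted at 0.5 passed the 2-fold threshold, and 0.0099% of unchanged genes did. The simulation holds no replicate spread and no tails wider than normal, so these shares do not say how many observed differences would repeat. Of 100 simulated lists of 20 genes, 4 fell outside the central 95% of random lists with no shift and 98 with a shift of 0.2, out of 19938 genes. Alternatives tried were median centring, a loess correction of the difference on the mean (span 0.3), other brightness filters, the mean of a gene's probe sets, a 1.5-fold threshold, unmatched random lists, members unique to a list, and lists without their most extreme member. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.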

Results

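Gene expression was measured in plasmacytoid dendritic cells (pDCs), the dendritic cell type specialised in type I interferon production, from mouse bone marrow. The cells came from chimeric mice whose blood system had been rebuilt from fetal liver cells, either lacking the transcription factor Runx2 or wild-type, and were taken 2 months after reconstitution. They were sorted as CD11b-negative cells carrying BST2 and B220, and 250 ng of total RNA per sample was labelled for an Affymetrix Mouse Gene 1.0 ST array, which measures each transcript with probes spread along its length. There was 1 array per genotype, so no difference below has a replicate check, a standard error or a p-value. Column medians were 181.7 intensity units in the Runx2-deficient sample and 182.9 in the wild-type sample, over 35556 probe sets. The comparison asks which transcripts differ between pDCs with and without Runx2.

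Most transcripts were at similar levels on both arrays. Of 10337 named genes past the brightness filter, 82 were at least 2-fold higher and 121 at least 2-fold lower in the Runx2-deficient sample, and 90.0% lay within 0.5 of no difference on the log2 scale. The central 95% of these genes ran from -0.72 to 0.63, and the Pearson correlation of log2 values across all 19938 named genes, which are not independent replicates, was 0.987. At least 4-fold differences were seen for 9 higher and 30 lower genes. Antigen receptor genes and the listed genes of other blood lineages and of donor sex were then left out, a choice made after seeing the data. Of the rest, 75 genes were at least 2-fold higher and 89 lower. Genes of other lineages outside those lists, such as the platelet gene Ppbp, stayed in these counts. Runx2 itself was not analysed here, because no probe set carries its name in the annotation used, so the genotype labels could not be checked on the targeted gene. Of its relatives, Runx1 was at 11.15 in the wild-type and 11.62 in the Runx2-deficient sample on the log2 scale, Runx3 at 10.49 and 10.11, and their shared partner Cbfb at 10.05 and 10.01.

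**Figure D1:**
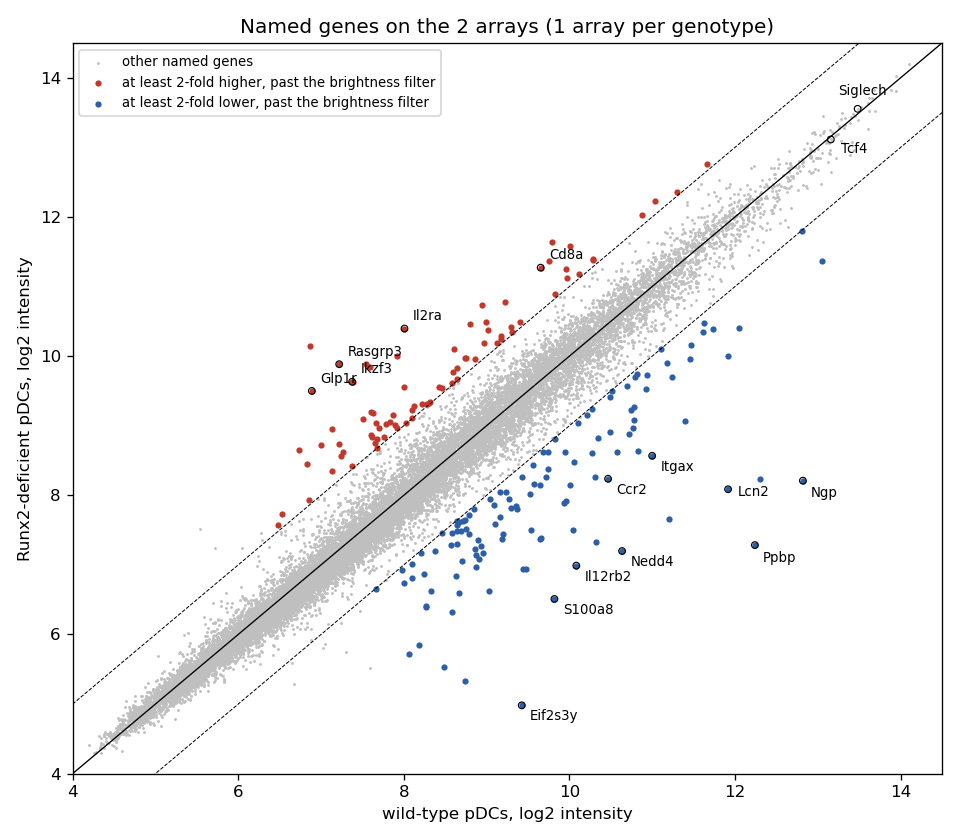
Log2 intensity of each named gene in wild-type pDCs (horizontal axis) and Runx2-deficient pDCs (vertical axis), 1 array each, with the line of no difference and dashed lines at 2-fold. The 82 genes higher and 121 genes lower by 2-fold and past the brightness filter are coloured; grey points beyond the dashed lines did not pass the filter. Siglech and Tcf4 lie on the line of no difference, while Itgax and Ccr2 lie below it.

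Of the genes highest in the Runx2-deficient sample relative to wild-type, the uncharacterised 1700048O20Rik was 9.68-fold higher, the Ras activator Rasgrp3 6.34-fold, the GLP-1 receptor gene Glp1r 6.11-fold and Il2ra, which encodes CD25, 5.23-fold. The small GTPase gene Rab30 was 5.09-fold higher, the lymphoid transcription factor Ikzf3 (Aiolos) 4.77-fold, the B cell scaffold gene Bank1 4.75-fold, Pcp4 4.73-fold and Fcmr, a receptor for IgM, 4.25-fold. Gimap4, a GTPase of lymphocytes, Cpq and Spon1 completed the 12 highest, at 3.78-fold, 3.60-fold and 3.53-fold. In 9 of these 12 genes, Rasgrp3, Glp1r and Ikzf3 among them, the wild-type level lay below the filter level of 7.61 on that array, so their folds rest on a dim denominator.

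Granule, platelet, Y-linked and signalling genes were among the lowest in the Runx2-deficient sample relative to wild-type. Ppbp, a platelet chemokine, was 31.0-fold lower in the Runx2-deficient sample, and the granule genes Ngp, Lcn2, S100a8, S100a9 and Ltf were 24.4-fold, 14.2-fold, 9.91-fold, 5.79-fold and 5.66-fold lower. The Y-linked Eif2s3y and Uty were 21.7-fold and 7.69-fold lower. The remaining 4 of the 12 lowest were the ubiquitin ligase gene Nedd4 (10.8-fold), the interleukin-12 receptor chain gene Il12rb2 (8.54-fold), the metalloproteinase inhibitor gene Timp2 (7.98-fold) and the glutamate receptor gene Grm8 (5.83-fold). In 10 of the 12, all but Ngp and Lcn2, the Runx2-deficient level lay below the filter level of 7.54. Antigen receptor genes, predicted genes and olfactory receptor genes were counted apart from this ranking. Of 16 antigen receptor genes past the filter, 2 were at least 2-fold higher and 5 lower; of 121 predicted genes, 1 was higher and 3 were lower; of 35 olfactory receptor genes, 0 were higher and 0 lower.

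The pDC-enriched list was slightly lower as a group in the Runx2-deficient sample, with 28 of 37 genes below 0, while 3 of the best known pDC genes were nearly equal. Siglech, a surface receptor of pDCs, was at 13.48 in the wild-type and 13.55 in the Runx2-deficient sample, Tcf4 (E2-2), the factor that specifies pDCs, at 13.16 and 13.11, and Irf8 at 13.40 and 13.43. Of the 37 genes, 2 were at least 2-fold lower, the receptor phosphatase gene Ptprs (-1.16) and the adhesion gene Cadm1 (-1.09), and 1 was at least 2-fold higher, the lymphoid DNA polymerase gene Dntt (1.10). The inhibitory receptor gene Lag3 differed by -0.74, Blnk by 0.52 and Havcr1 by 0.27. The list's median difference was -0.12, below the -0.089 to 0.095 that held the central 95% of expression-matched random lists (percentile 0.70). Marker sets of other cell types also differed on these arrays, with medians of -1.74 (granulocyte), -0.78 (erythroid), -0.51 (12 platelet genes) and 0.22 (T cell). In the T cell list, Cd3d, Cd3e and Cd3g were below the filter on both arrays and below 0. Its median therefore does not show a difference in T cell RNA. Of the surface proteins stained for the sort, Bst2 differed by -0.31, Ptprc, which encodes the B220 protein, by 0.13 and Itgam (CD11b) by -0.29 with both levels below the filter. Itgax, which encodes CD11c, a protein that was stained but is not part of the stated gate, was 5.39-fold lower, at 2047 intensity units in the wild-type and 379 in the Runx2-deficient sample. The median of these 4 genes, -0.30, lay at percentile 2.48 of its random lists, and at 5.34 without Itgax.

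Single chemokine receptor genes differed, while their list did not stand apart. Ccr2, a receptor that guides monocytes out of the bone marrow, was 4.69-fold lower in the Runx2-deficient sample, at 10.47 against 8.24. Ccr7, which directs cells to lymph nodes, was 2.56-fold higher. Cxcr4, the receptor for the marrow retention signal CXCL12, differed by 0.62, Cxcr3 by 0.64 and Cmklr1 by -0.55, all below 2-fold. Of 25 chemoattractant receptor genes, 1 was at least 2-fold higher and 2 lower, the other being the neutrophil receptor gene Cxcr2 at levels below the filter, and the list's median of -0.081 lay within its random lists (percentile 19.7). Among 26 adhesion genes, Itgax was the only one 2-fold apart, Itgb7 and Itgal, integrin chains of lymphocytes and dendritic cells, differed by -0.87 and -0.83, and Icam2, Vcam1 and Itgb3 by 0.52, 0.49 and 0.38. The adhesion median was -0.082, at percentile 13.7.

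Antigen presentation genes differed in both directions. H2-Ab1, an MHC class II chain, was 2.01-fold lower in the Runx2-deficient sample, Ciita, the master activator of class II genes, differed by -0.87 and H2-Eb1 by -0.55. H2-Ob, a modulator of peptide loading, and the costimulatory genes Cd86 and Cd40 differed by 0.79, 0.58 and 0.49. The median of the 12 measured genes was -0.30, at percentile 0.050 of random lists, on arrays where the granulocyte and erythroid medians were -1.74 and -0.78. Of 35 conventional dendritic cell genes, Cd8a (3.07-fold), Ccr7 and Btla (2.09-fold) were at least 2-fold higher and Itgax was the 1 at least 2-fold lower, while Naaa and Gcsam differed by -0.87 and -0.36. That list's median was 0.053 at percentile 98.3, and it moved to percentile 78.8 when the difference was corrected for its trend with intensity. Over members past the filter it was 0.12, at percentile 97.3. Of 27 dendritic cell transcription factor genes, Ikzf3 was the 1 at least 2-fold apart, Spib, Cbfa2t3 and Spi1 differed by -0.69, -0.61 and -0.49, Id3 and Myb by 0.57 and 0.22, and the median of -0.087 lay at percentile 13.3.

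Interferon-stimulated genes were higher as a group in the Runx2-deficient sample. Of 30 measured genes, 21 were above 0 and 2 at least 2-fold higher, Ifit2 (1.14) and Iigp1 (1.09), with Mx2 at 0.92. Irf7, the main inducer of type I interferon in pDCs, Rsad2 and Cmpk2 differed the other way, by -0.68, -0.54 and -0.43. The median of 0.26 lay above the -0.14 to 0.068 range of random lists and above each of the 10000 draws. On the same arrays the granulocyte and erythroid lists had medians of -1.74 and -0.78, and 12 platelet genes -0.51. The T cell list had 0.22 (percentile 99.99), which does not show a difference in T cell RNA, since Cd3d, Cd3e and Cd3g were below the filter. Genes of TLR7 and TLR9 signalling, the nucleic acid sensing route of pDCs, had 0 of 21 members 2-fold apart. Irf7, Plscr1 and Irak2 differed by -0.68, -0.63 and -0.52, and Tlr7, Traf6 and Ifnar1 by 0.24, 0.23 and 0.14, and the median of -0.15 lay at percentile 1.48, and at 2.52 without Irf7. Of 32 cytokine and cytokine receptor genes, 2 were at least 2-fold higher, the stem cell factor receptor gene Kit (2.92-fold) and the chemokine gene Ccl3 (2.22-fold), with Cxcl10 at 0.82. Tgfb1, Csf2rb and Csf2rb2 differed by -0.53, -0.53 and -0.48, and the list's median of 0.20 lay above each of its random lists. It was 0.34 over members past the filter and 0.091, at percentile 99.5, over members of no other list.

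Cell cycle genes were lower as a group. Of 29 measured genes, 27 were below 0 and 2 at least 2-fold lower, the mitotic kinase genes Plk1 (2.25-fold) and Aurkb (2.08-fold), with the cyclin gene Ccnb2 at -0.89. Mcm7 and Bub1b, at 0.13 and 0.0040, were the 2 members above 0. The median of -0.38 lay below each random list. Granulocyte precursor and erythroid genes were lower on the same array, with medians of -1.74 and -0.78. Of 21 ribosomal protein genes, 0 were 2-fold apart and 16 were above 0, with Rpl5, Rpsa and Rps9 at 0.61, 0.50 and 0.45, Rps19, Rpl23 and Rplp0 at -0.18, -0.074 and -0.052, and a median of 0.14 at percentile 99.1.

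Genes of other cell types differed by type. Of 18 neutrophil and granulocyte precursor genes, 15 were at least 2-fold lower in the Runx2-deficient sample and 0 were 2-fold higher. Of 13 erythroid genes, 5 were at least 2-fold lower, among them the anion exchanger gene Slc4a1 (4.81-fold) and the carbonic anhydrase gene Car2 (4.20-fold), with Rhag 4.23-fold lower at levels below the filter. Tfrc, the transferrin receptor gene, differed by 0.44. Both medians lay below each random list, and the erythroid one was -1.24 over members past the filter. The T cell list had a median of 0.22 at percentile 99.99, with Cd8a 3.07-fold higher, Lat and Cd4 at 0.98 and 0.76, Thy1 2.78-fold lower, and Cd3e and Bcl11b at -0.34 and -0.12. Cd3d and Cd3g, at -0.11 and -0.028, were below the filter on both arrays, as was Cd3e. Cd4 and Cd8b1 were bright, at 11.42 and 11.10 in the wild-type sample. The B lineage list went both ways, with Bank1 and Cd22 (2.94-fold) at least 2-fold higher, Fcrla at 0.84, Blk (2.85-fold) and Cd72 (2.82-fold) at least 2-fold lower, Spib at -0.69, and a median of -0.10 at percentile 12.5. Monocyte and macrophage genes had a median of -0.081 at percentile 27.8, with Ccr2 and Lyz2 (-1.59) at least 2-fold lower, Fn1 at -0.88, and C1qb and Csf1r at 0.89 and 0.64. NK cell genes had a median of 0.051 at percentile 97.3, with Klra8 and Klrk1 2.89-fold and 2.11-fold higher, Klra8 below the filter.

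The lists that follow here lay within their random lists. Plasma cell genes had a median of 0.094 (percentile 91.8), with Sdc1 (CD138) at 0.91 and Xbp1 at -0.22. Basophil and mast cell genes had a median of -0.037 (percentile 54.9), with Kit high and Mcpt8 at -0.59. Progenitor genes had a median of -0.014 (percentile 71.5) but a mean of 0.086, with Kit and Erg (0.99) high and Adgrg1 at -0.64. Immediate-early and stress genes had a median of 0.11 (percentile 97.3), with Hspa1a and Egr1 2.12-fold and 2.02-fold higher and Klf2, Fosb and Nr4a1 at -0.95, -0.79 and -0.71. Apoptosis and survival genes had a median of 0.044 (percentile 80.7), with the survival gene Bcl2 at -0.98 and Birc2 at 0.57. Genes of the unfolded protein response and secretion had a median of 0.050 (percentile 78.1), with Ddit3 at 0.49 and Sdf2l1 at -0.50. Mitochondrial oxidative phosphorylation genes had a median of -0.021 (percentile 37.6) and a mean of 0.020, with Cox4i1 2.10-fold higher and Cox6c at -0.33. Runx2 targets known from osteoblasts had a median of -0.10 (percentile 18.8), with 0 of 14 genes 2-fold apart and Tnfsf11 (RANKL) furthest from 0, at -0.46. The 3 measured Runx family genes had a median of -0.045 (percentile 36.2) and a mean of 0.016.

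The sex-linked list had the median furthest from 0 of the 28 lists. Eif2s3y, Uty and Kdm5d, all on the Y chromosome, were at 9.42, 8.48 and 8.58 in the wild-type sample and at 4.98, 5.54 and 6.32 in the Runx2-deficient sample. Xist, which is transcribed from the inactive X chromosome, was at 13.06 and 13.46. The list's median of -2.60 lay below each random list.

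**Figure D2:**
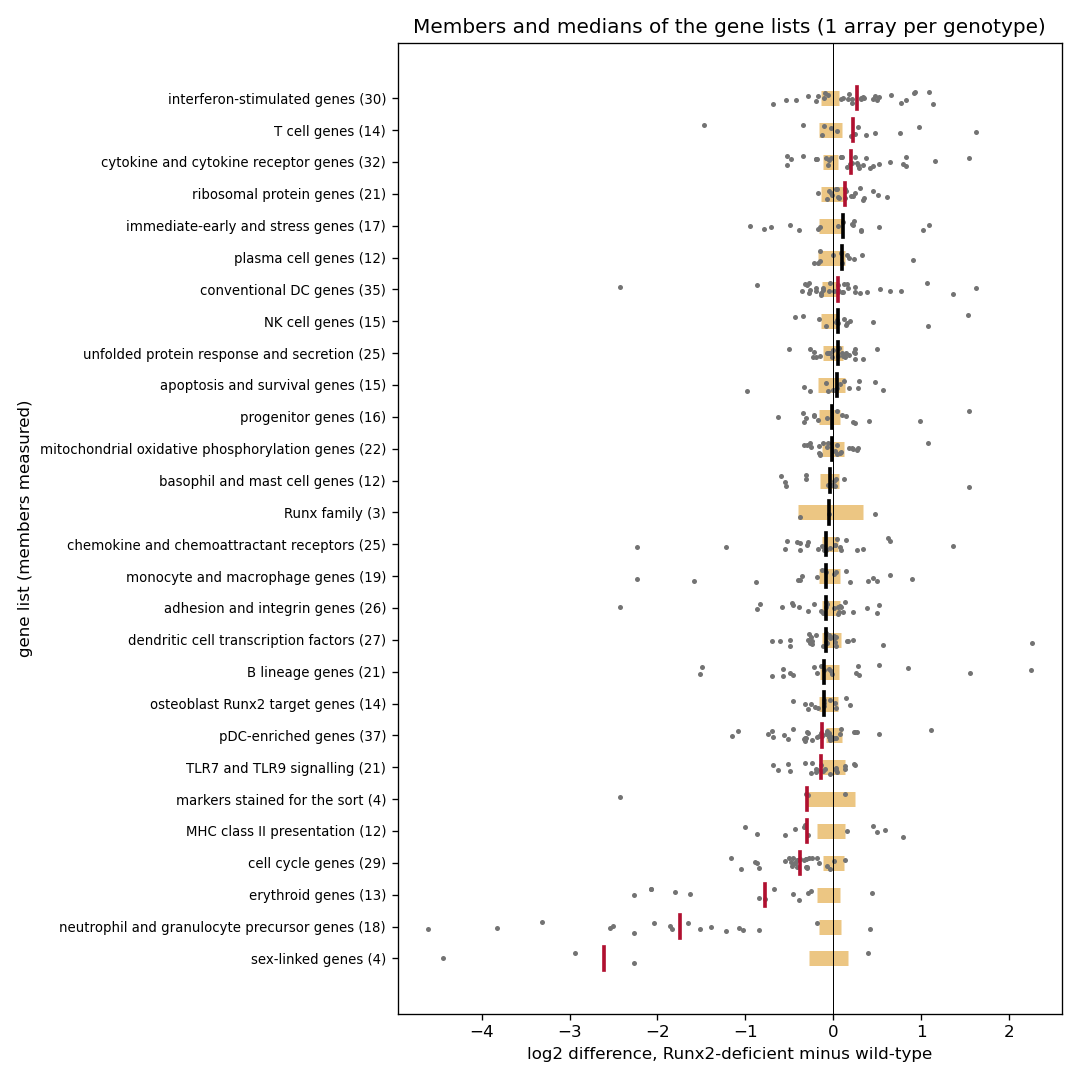
Log2 difference, Runx2-deficient minus wild-type, of each member (grey points) of the 28 gene lists, 1 array per genotype; vertical bars are list medians, red where they lie outside the central 95% of 10000 random lists matched on mean expression (orange bands) and black otherwise. Points are spread vertically only to separate them. The sex-linked, neutrophil and erythroid medians lie lowest, at -2.60, -1.74 and -0.78, and the interferon-stimulated median highest, at 0.26.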

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

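The tests below of the other cell lists as a whole, of the Y-linked genes themselves and of the sources of Ccr2 and Itgax were chosen after the values were seen; the tests on further granulocyte, erythroid and X-linked genes and on the intensity trend were fixed before their results. The test of a general rise of other cells was recast more than once after the values were seen, the last time to genes at comparable levels. Bounds written against monocyte and conventional dendritic cell RNA were met, but they are set aside, a choice also made after the values were seen, because their members go both ways and many are too dim or too bright on both arrays to show a small share. With 1 array per genotype, an effect of Runx2 loss on any of these genes remains open and untested.

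Probe sets without a gene name, or with several, were not used in the gene comparison. Of 6717 past the brightness level, 323 (4.8%) were at least 2-fold higher and 58 (0.86%) at least 2-fold lower in the Runx2-deficient sample. Among named genes the shares were 0.79% and 1.17%, with more lower than higher. Of the higher ones among the unused probe sets, 321 have no gene name, and 251 of these have identifiers below the lowest identifier with a name. So do 20 of the 51 lower ones without a name and 3890 of all 5888 without a name past that level. The annotation used does not say what these probe sets measure. Their excess is therefore not read as genes that rise, and its cause was not tested.

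Granulocyte precursor and erythroid genes were lower on the Runx2-deficient array, with 15 of 18 and 5 of 13 at least 2-fold lower. An intensity-dependent difference in scaling is argued against, because the granulocyte median was -1.69 after the trend was removed. A lower share of pDCs in the wild-type sample that raises every other cell type alike could not be decided. For this, 24 genes of 6 other cell types past the brightness filter were compared with the granulocyte list. They were no brighter in the Runx2-deficient sample than the granulocyte genes that were 2-fold lower. Their median was -0.13 (quartiles -0.51 and 0.19), while the granulocyte list had quartiles of -2.44 and -1.11. But granulocyte genes outside that list had a median of only -0.24. Genes of a cell type can thus differ this little while its listed genes differ strongly. RNA of granulocyte precursors and of erythroid cells in the wild-type sample cannot be told apart from a change within the sorted cells: granulocyte genes outside the list had a median of -0.24 (15 of 19 below 0) and erythroid ones -0.41 (16 of 17 below 0), both below each random list but short of the -0.5 set beforehand, and many of them are dim. The stated sort gate on CD11b, BST2 and B220 is meant to leave out mature granulocytes and red cell precursors, but how completely it did so was not tested here.

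Y-linked genes were lower on the Runx2-deficient array. Eif2s3y, Uty and Kdm5d lie on the Y chromosome and were above the filter level in the wild-type sample, at 9.42, 8.48 and 8.58. That sample therefore held cells of male origin. All 3 genes were below the filter level in the Runx2-deficient sample, at 4.98, 5.54 and 6.32, with Kdm5d differing least, by -2.27. Scarce cells of male origin there would give this, but that is the pattern itself, and no separate test of it was made. Xist at 13.06 in the wild-type sample goes with cells of female origin in it too. The Y-linked levels, and Xist at a difference of 0.39, go with a larger share of female cells in the Runx2-deficient sample. X-linked genes that escape inactivation cannot decide this. Their median was 0.10, within the -0.29 to 0.26 of random lists, and rests on only 5 genes. The sample labels used here give no sex, so a difference in sex between the samples cannot be separated from genotype for any gene.

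Ccr2 and Itgax were lower on the Runx2-deficient array. RNA of monocytes in the wild-type sample cannot be told apart from a change within the sorted cells. The other 18 monocyte genes had a median of -0.039 (quartiles -0.32 and 0.34). Lyz2 at -1.59 and Fn1 at -0.88 go with such a source, while C1qb at 0.89 and Csf1r at 0.64 go the other way. RNA of conventional dendritic cells is left open in the same way, with a median of 0.054 over the other 34 genes (quartiles -0.18 and 0.24). Naaa was at -0.87, while Cd8a, Ccr7 and Btla were at 1.62, 1.35 and 1.06. Granulocyte precursors cannot be told apart as a source, since neither array holds these cells alone and the Ccr2 difference of -2.23 goes with theirs.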

How the results depend on the processing

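No paired analysis was possible because each genotype has 1 array, and no replicate could be left out. Under a brightness filter at the 75th percentile 132 genes were 2-fold apart, 76 of them lower, against 203 and 121; these counts fall because fewer genes pass the filter. At 1.5-fold, 711 genes differed, 312 higher and 399 lower. Of the 13 lists outside the central 95% of random lists, 10 stayed outside under every alternative that gave a value. The median of the stained markers left it in 5 settings: -0.26 with median centring, -0.26 with loess, -0.31 with bright members only, -0.30 with mean probe sets and -0.29 without Itgax. The conventional dendritic cell median did so at 0.034 with loess, 0.12 with bright members and 0.056 with unshared members, and the TLR7 and TLR9 median at -0.13 without Irf7. The plasma cell median of 0.094 lay outside with unmatched lists, the NK median with loess (0.11), and the immediate-early median with centring (0.15), loess (0.15), mean probe sets (0.11) and unmatched lists (0.11). The causes were not tested. Of 162 alternative values for the 54 named genes 2-fold apart, 2 dropped under 2-fold and 0 changed sign. Lists of under 3 genes gave no value: the Runx family without its most extreme member and the stained markers without shared members. Centring subtracted a median of -0.033, and the loess curve ran from -0.080 to 0.054. Without a detection call, dim levels are only as reliable as the brightness filter.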

Other observations

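Of 8 further gene families looked at after the values were seen, those with members of interest are described here by their values only, because families picked in this way cannot be tested on the same arrays. All 8 measured GIMAP genes, which encode GTPases of lymphocytes, were above 0 in the Runx2-deficient sample, with a median of 0.49 and Gimap6 and Gimap9 at 0.92 and 0.93 beside Gimap4. The interferon-inducible Ifi200 family had a median of 0.35 over 10 genes, with Ifi213 3.07-fold higher. Receptors of the SLAM family went both ways: Slamf7 was 3.05-fold higher, Cd244a (2B4) 3.86-fold and Slamf9 2.83-fold lower, and the median of 9 genes was 0.067. Sh2d1b1, an adaptor of SLAM receptors, was 5.04-fold lower. Among 36 genes whose symbols begin as interleukin receptors, Il2ra and Il13ra1 (3.03-fold) were at least 2-fold higher and Il12rb2 and Il17rb (3.15-fold) lower, with a median of -0.082. The remaining 4 families had medians of 0.046 (Klr receptors), 0.027 (Tnfrsf), -0.094 (kallikreins) and -0.13 (S100). The costimulatory receptor gene Cd27 was 3.18-fold higher, and Havcr2 (TIM-3) 3.32-fold lower. Platelet and megakaryocyte genes other than Ppbp were lower in 12 of 12 cases, with a median of -0.51 and Pf4 2.42-fold lower.

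Immunoglobulin kappa variable genes differed in both directions. Igkv4-91 was 16.7-fold and Igkv6-20 11.6-fold lower in the Runx2-deficient sample, and Igkv19-93 was 2.14-fold higher on its brighter probe set. The constant region gene Ighg3 was 10.6-fold lower, while the plasma cell list lay within its random lists.

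One hypothesis was that a chromosome segment around Runx2 that differs in strain origin, or chromosome segments elsewhere that differ between the samples, may account for some genes 2-fold apart that neighbour each other. Of the 200 measured genes nearest to Runx2 in chromosome order, 2 were 2-fold apart and past the brightness filter, Enpp5 and Trem3. The central range was 0 to 4 in 1000 expression-matched shuffles, so these data cannot decide the hypothesis there. Rhag, also among the 200, was 4.23-fold lower at levels below the filter. Enpp4, Clic5 and Supt3, which follow Enpp5 in chromosome order, differed by 0.68, 0.71 and -0.10, values picked after they were seen. The fullest window of 50 neighbouring genes held 7 genes 2-fold apart and past the brightness filter (central range 3 to 6). But 5 of them were immunoglobulin kappa genes, which makes that test void. Without antigen receptor genes the fullest window held 5, at percentile 85.6 of shuffles: Iqcb1, Upk1b, Zbtb20, Mir568 and Cd200r1, all higher in the Runx2-deficient sample. The window scan over all genes was chosen after the values were seen, and the scan without antigen receptor genes and the Runx2 neighbourhood before.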
